A study of Mus musculus with 15 samples.

How the data were processed

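RNA was measured in LSK cells (negative for the lineage markers Ter119, CD11b, Gr-1, CD19 and CD3, positive for Sca-1 and c-Kit) sorted by flow cytometry from the bone marrow of 8-week-old VavCre mice, in 5 groups of 3 libraries. Per the labels, RNA was extracted with RNeasy Micro columns and libraries were made with the TruSeq Stranded mRNA kit. The authors' processing notes name Trimmomatic, STAR and Subread without versions. Per the file headers, the deposited values are gene counts made by featureCounts 1.5.1 from exon features grouped by gene ID, with a modified copy of the GENCODE M13 annotation on GRCm38.p5. No strand option was set per the file headers, so reads of both strands were counted together although the kit is stranded, and reads that map to several places were not counted. The deposited counts were whole numbers for 50686 genes in each file and were used as given. No reads were available, so no alignment or count was redone, and the Jak2 allele could not be read.

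Library totals ranged from 8533842 to 18179023 counts. At these depths a count of 0 allows up to 3 counts, which is 0.269 CPM in double-mutant library 1, and such limits and counting intervals cover counting error only. Of the 50686 genes, 27358 had a count in at least 1 library. Gene IDs were joined to symbols and coordinates by ID, 310 IDs had no symbol, and 68 symbols were shared by several IDs, which were kept as separate genes.

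Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 13823 genes. Libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 15 libraries together (10 residual degrees of freedom). There were 7 comparisons: Jak2VF with wild-type, Cdk6KO with wild-type, the double mutant with Jak2VF, with Cdk6KO and with palbociclib-treated Jak2VF, treated with untreated Jak2VF, and the interaction of Jak2VF with Cdk6KO. P-values were adjusted within each comparison by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Fold changes are those of edgeR with its prior count of 0.125. CPM values were computed from the counts of the tested genes with the TMM factors, and SDs are between libraries. Xist, summed Y-linked and late granulocyte values per library are scaled to the total counts alone.

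Gene lists (27 lists, 758 genes) were written before the data were examined and tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of each comparison. The lists were written from general knowledge, share some genes, and were not taken from these libraries. Each list was also tested with a correlation estimated from the data and with fry, a self-contained test. Members were also adjusted over the list alone.

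The genes named in the text follow a rule set before the data were examined. It names Cdk6 and Jak2. Among called genes whose libraries do not overlap between the groups, with a mean of at least 5 CPM in the higher group, it names the 10 largest changes in each direction (6 for the interaction). Predicted genes, clone names, pseudogenes, mitochondrial genes, immunoglobulin and T cell receptor segments and sex-linked genes are left out of that part. Per list it names up to 4 called members with the largest change, or, where none was called and the list is mentioned, the 2 members with the smallest p. Fewer genes are named in the text than the rule allows, and these genes and the lists given for each comparison were selected with their values known. Genes outside the rule are said to be chosen after their values were seen.

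Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library in turn, and fitting only the groups compared. After the data were examined these were added: fits without the palbociclib-treated libraries, without 2 of them, without the Xist-positive libraries of other groups, with Y-linked or late granulocyte expression as a covariate, and with a length trend removed per library. The effect of shared libraries on overlaps was simulated with 20 data sets that held no effect of Cdk6 loss or palbociclib.

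The procedure was tested on simulated data modelled on Jak2VF and wild-type, in which 200 of 13823 genes were changed. At 1.5-fold, 2-fold and 4-fold, edgeR recovered 22.4%, 58.2% and 87.9% of them with 7 false calls (5.88% of its calls). DESeq2 recovered 44.8%, 73.1% and 90.9% with 33 false calls (19.2%), and limma-voom 20.9%, 58.2% and 84.8% with 8 (6.84%). Camera called 0 of 40 unchanged simulated lists. The simulated genes were drawn independently of each other, so this count does not show its error rate among correlated genes. Replicate numbers were checked for pairing: 6 of 15 libraries correlated best with a library of their own number, so the numbers were treated as names only. No library was left out of the tests.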

Results

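Gene expression was measured by RNA sequencing in LSK cells, the lineage-negative, Sca-1-positive, c-Kit-positive fraction of mouse bone marrow that holds hematopoietic stem cells and the earliest multipotent progenitors. The cells were sorted from 8-week-old mice that carried VavCre, a recombinase active in blood cells. Jak2VF denotes the constitutively active Jak2 kinase allele found in myeloproliferative neoplasms, and Cdk6KO denotes loss of Cdk6, a cyclin-dependent kinase of the G1 phase that also acts on transcription. The 15 libraries formed 5 groups of 3: wild-type, Jak2VF, Cdk6KO, the double mutant with both changes, and Jak2VF mice given palbociclib, an inhibitor of the kinases CDK4 and CDK6, at 38 mg/kg 3 times in a week. Library totals were 9284579 to 11189499 counts in wild-type, 8533842 to 11516324 in Jak2VF, 10369258 to 15064745 in Cdk6KO, 9141439 to 11183794 in double-mutant and 10513972 to 18179023 in palbociclib-treated libraries. Levels are given as CPM (counts scaled to library size and TMM factors) with the SD over n = 3 libraries, and changes as log2 fold changes with their standard error (SE) from the edgeR fit. The labels do not number the animals behind each library, so each p-value measures the spread between these libraries.

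Cdk6 (ENSMUSG00000040274.11, GRCm38 chromosome 5, 3341485 to 3531008) was counted at 582 ± 19.8 CPM in wild-type and 606 ± 9.64 CPM in Jak2VF libraries. It was at 195 ± 35.6 CPM in Cdk6KO and 207 ± 39.4 CPM in double-mutant libraries, and gene counts do not show which exons the counts of the knockout libraries came from. Palbociclib-treated libraries held 691 ± 133 CPM of Cdk6. Jak2 (ENSMUSG00000024789.12, chromosome 19, 29251828 to 29313080) lay between 89.6 and 104 CPM in every group mean and was called in none of the comparisons (edgeR adjusted p = 0.624 for Jak2VF with wild-type). Gene counts do not show which allele was transcribed.

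**Figure D1:**
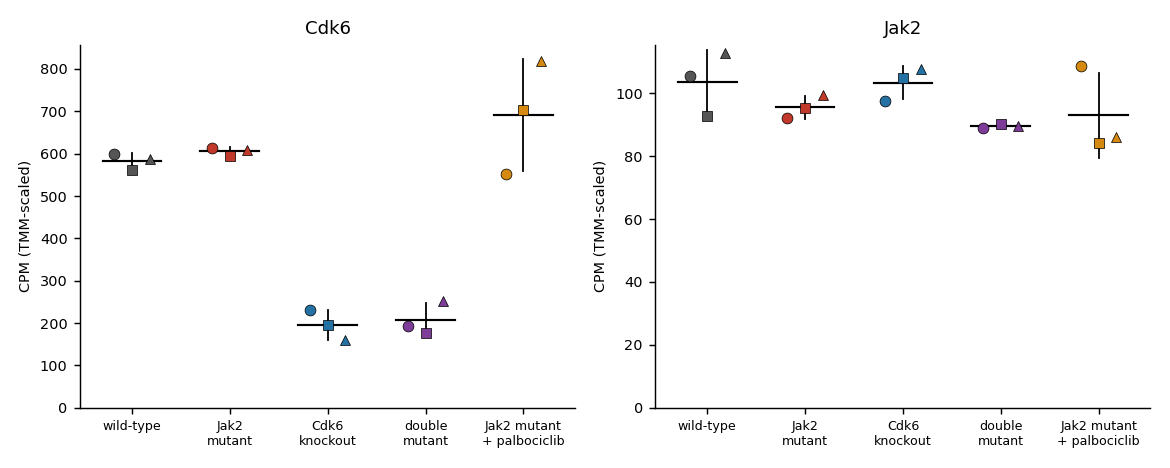
CPM of Cdk6 and Jak2 in each of the 15 libraries by group (circle, square and triangle for replicates 1, 2 and 3; horizontal line, group mean; vertical line, ± SD). Cdk6 was at 195 and 207 CPM on average in the Cdk6KO and double-mutant groups and at 582 to 691 CPM in the others, while the group means of Jak2 stayed between 89.6 and 104 CPM.

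Some libraries stood apart within their group. The CPM values of this paragraph and its figure are scaled to library totals alone, without TMM factors. All 3 palbociclib-treated libraries had Xist, the RNA of the inactive X chromosome, at 648, 711 and 1181 CPM and at most 0.285 CPM summed over 4 Y-linked genes. Double-mutant library 1 had Xist at 845 CPM and no Y-linked counts, where a count of 0 allows up to 3 counts. Wild-type library 3 had both, with Xist at 633 CPM and Y-linked counts at 49.1 CPM, 21.3% of the highest library. The other 10 libraries held at most 2.24 CPM of Xist and 159 to 230.4 CPM of Y-linked counts. Late granulocyte genes, taken as the mean log2 CPM of 10 genes such as S100a8, S100a9 and Ltf, were at 11.27 and 10.54 in palbociclib-treated libraries 1 and 2 and at 6.54 in library 3. In Jak2VF they were at 5.17, 8.72 and 10.02, and in wild-type at 5.12, 5.02 and 7.30.

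**Figure D2:**
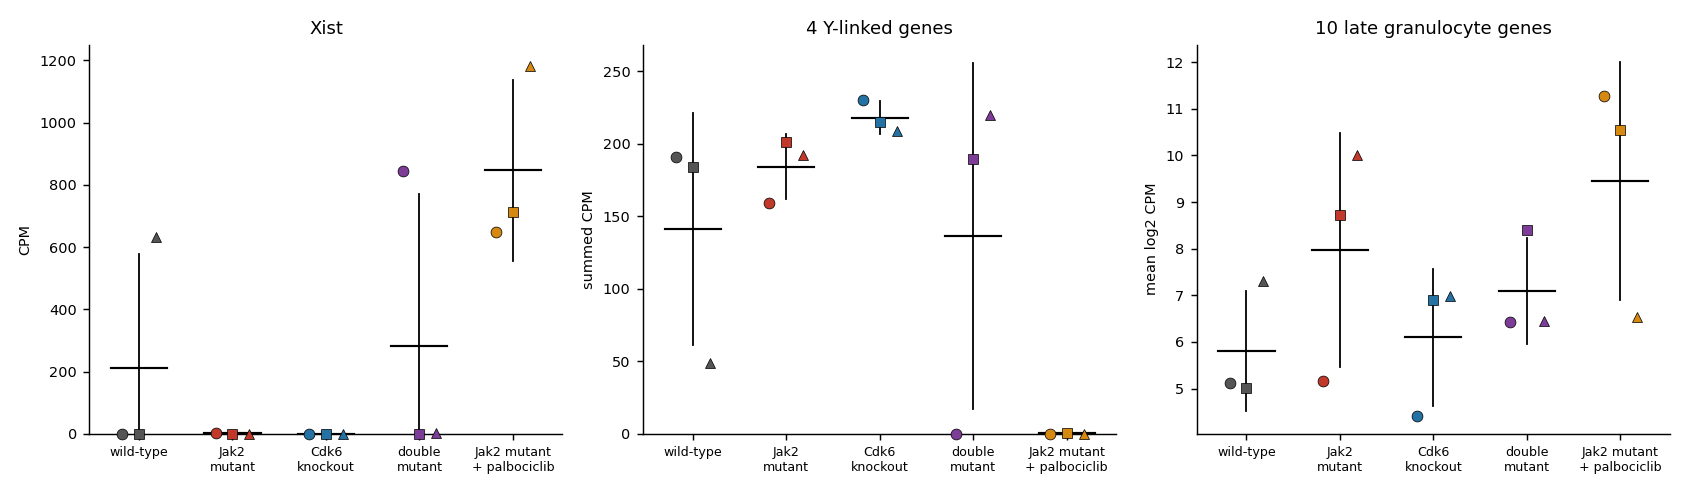
Xist (CPM), 4 Y-linked genes summed (CPM) and the mean log2 CPM of 10 late granulocyte genes in each of the 15 libraries by group, scaled to library totals without TMM factors (circle, square and triangle for replicates 1, 2 and 3; horizontal line, group mean; vertical line, ± SD). The 3 palbociclib-treated libraries and double-mutant library 1 hold Xist at 648 to 1181 CPM with nearly no Y-linked counts, and late granulocyte genes range from 6.54 to 11.27 among the treated libraries.

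Jak2VF was compared with wild-type to ask what the Jak2 mutant allele changes in LSK cells while Cdk6 is present. Single genes of cytokine feedback rose and single genes of early lymphoid cells fell. Socs2, a feedback inhibitor of cytokine receptors induced by STAT5 (chromosome 10, 95385362 to 95417180), rose 2.87-fold, from 8.29 ± 0.973 to 23.8 ± 1.81 CPM (log2 1.52, SE 0.17, edgeR adjusted p = 0.00152). Podxl, the sialomucin podocalyxin (chromosome 6, 31519488 to 31563981), rose 6.96-fold, from 4.65 ± 0.942 to 32.5 ± 6.93 CPM (log2 2.80, SE 0.33, edgeR adjusted p = 0.00208). Id1, an inhibitor of basic helix-loop-helix factors (chromosome 2, 152736251 to 152737410), rose 6.01-fold to 9.65 ± 0.943 CPM (log2 2.59, SE 0.41, edgeR adjusted p = 0.00896). Il7r, the interleukin-7 receptor of lymphoid progenitors (chromosome 15, 9506161 to 9529876), was 3.91-fold lower at 12.8 ± 2.01 against 50.07 ± 3.39 CPM (edgeR adjusted p = 0.0281).

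Among called genes with a mean of at least 5 CPM in the higher group, the largest rise belonged to Ttc9, a tetratricopeptide repeat protein (ENSMUSG00000042734.6, chromosome 12, 81631249 to 81667557), which was at 0.154 ± 0.0435 CPM in wild-type and 11.9 ± 1.16 CPM in Jak2VF. Its counts were 5 over the wild-type and 357 over the Jak2VF libraries, a ratio of 76.7 with a 95% exact (Clopper-Pearson) counting interval of 32.6 to 238. Also higher were Egr4, an immediate early zinc finger gene (15.4-fold, to 6.80 ± 3.49 CPM), Gdf15, a stress-induced cytokine (9.73-fold, to 12.2 ± 5.68 CPM), Gadd45g, a stress-response gene (4.50-fold), Tjp1, a tight-junction protein (3.64-fold), and Slc7a8, an amino acid transporter (2.73-fold), with edgeR adjusted p between 0.00152 and 0.0340. Lower were Ddx4, an RNA helicase known from germ cells (5.01-fold, to 8.66 ± 1.59 CPM), and St8sia1, a ganglioside sialyltransferase (4.43-fold, to 2.90 ± 0.296 CPM). Pou2af1, a coactivator of immunoglobulin gene transcription, and Irf4, a lymphoid transcription factor, were lower by 4.73-fold and 4.66-fold.

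Lymphoid lists moved down. Of 19 lymphoid-primed progenitor genes measured, 8 fell and 11 did not pass, and 16 fell adjusted over the list alone. Examples are Ccr9, a homing receptor (6.76-fold lower), Rag1, the V(D)J recombinase (4.29-fold lower, 73.0 ± 2.97 to 17.03 ± 2.29 CPM), and Blnk, an adaptor of the B cell receptor (3.76-fold lower). The list's median log2 change was -1.13 (camera, adjusted p = 4.07e-12), with adjusted p = 0.179 with an estimated correlation. Of 19 B-lineage genes, 7 fell and 12 did not pass, and 14 fell adjusted over the list alone. Pax5 and Ebf1, transcription factors of B cell commitment, fell 5.20-fold and 4.18-fold, and Blk, a B cell kinase, fell 4.64-fold. That list's median was -1.76 (camera, adjusted p = 4.07e-12), with adjusted p = 0.123 with an estimated correlation.

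Megakaryocyte and cytokine-response lists moved up. Of 30 megakaryocyte genes, 6 rose and 24 did not pass, and 12 rose and 1 fell adjusted over the list alone. Itga2b, the platelet integrin alpha chain, rose 2.34-fold from 71.3 ± 14.5 CPM, its partner chain Itgb3 rose 2.31-fold, Selp, which encodes P-selectin, rose 3.04-fold, and Rab27b, which acts in granule release, rose 2.21-fold. The median log2 change was 0.86 (camera, adjusted p = 9.76e-10), with adjusted p = 0.227 with an estimated correlation. Among 22 JAK-STAT5 target genes 3 rose, namely Socs2, Id1 and Socs3, a cytokine feedback inhibitor that rose 2.17-fold to 68.6 ± 3.73 CPM, and 6 rose adjusted over the list alone. Camera gave this list an adjusted p = 0.00845, with adjusted p = 0.369 with an estimated correlation. In the mast and basophil list 1 of 12 genes rose, Slc18a2, a monoamine transporter (2.11-fold), and 6 rose adjusted over the list alone (camera, adjusted p = 1.04e-05; adjusted p = 0.123 with an estimated correlation). Gata2, a stem cell transcription factor, rose 1.74-fold and was the single called gene of 39 stem cell and quiescence genes, of which 10 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.000218; adjusted p = 0.569 with an estimated correlation).

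The NF-kB and granulocyte-monocyte lists had no called member in edgeR. Of 42 NF-kB pathway and target genes, 33 were higher, 10 of them and 1 lower gene at an unadjusted p under 0.05, and DESeq2 called 1. Il1b, a proinflammatory cytokine, was at 110.2 ± 73.6 against 7.86 ± 7.65 CPM (edgeR adjusted p = 0.175), and Bcl3, an NF-kB cofactor, at 26.4 ± 4.84 against 15.9 ± 1.30 CPM (edgeR adjusted p = 0.134). Camera gave the NF-kB list an adjusted p = 0.00379, with adjusted p = 0.569 with an estimated correlation. Of 37 granulocyte-monocyte genes 19 were higher at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 2. Their median log2 change was 1.49 (camera, adjusted p = 3.47e-07; adjusted p = 0.569 with an estimated correlation). The 10 late granulocyte genes ranged from 5.17 to 10.02 among the Jak2VF libraries. The difference in the mean log2 CPM of the granulocyte-monocyte list was 1.30, 1.98 without Jak2VF library 1 and 0.796 without Jak2VF library 3. Pro-apoptotic genes did not pass (camera, adjusted p = 0.0759) but did without Jak2VF library 3 (camera, adjusted p = 0.0490) and with fry (adjusted p = 0.0113). Not passed either were anti-apoptotic, G2/M (camera, adjusted p = 0.943 for both) and E2F and S-phase genes (camera, adjusted p = 0.828). The direction of these last 3 lists turned when single libraries were left out, and the E2F and S-phase list passed, lower, without Jak2VF library 1 (camera, adjusted p = 0.0444). Of the 63 list results followed under alternatives, the pro-apoptotic one is the only 1 that fry newly passed. Fry lost 40 of the camera calls among them.

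In all, edgeR called 253 of 13823 genes between Jak2VF and wild-type, 78 higher and 175 lower. Leaving out any 1 of the 6 libraries gave 52 to 111 calls, and of the 27 called genes named here 8 to 16 stayed called. Ttc9, Podxl, Socs2, Slc7a8, Itga2b, Ddx4 and St8sia1 stayed called in each of those fits. Without wild-type library 3 and double-mutant library 1, which held Xist counts, 38 genes were called. More were called by DESeq2 (640), and by edgeR without the palbociclib-treated libraries (908) or with only the groups compared (697). Of the 175 lower genes, 46.3% belonged to the tenth of genes with the longest exonic length (at least 9089 bases), against 3.85% of the higher genes. The Spearman correlation of the change with exonic length over all genes tested was -0.22.

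**Figure D3:**
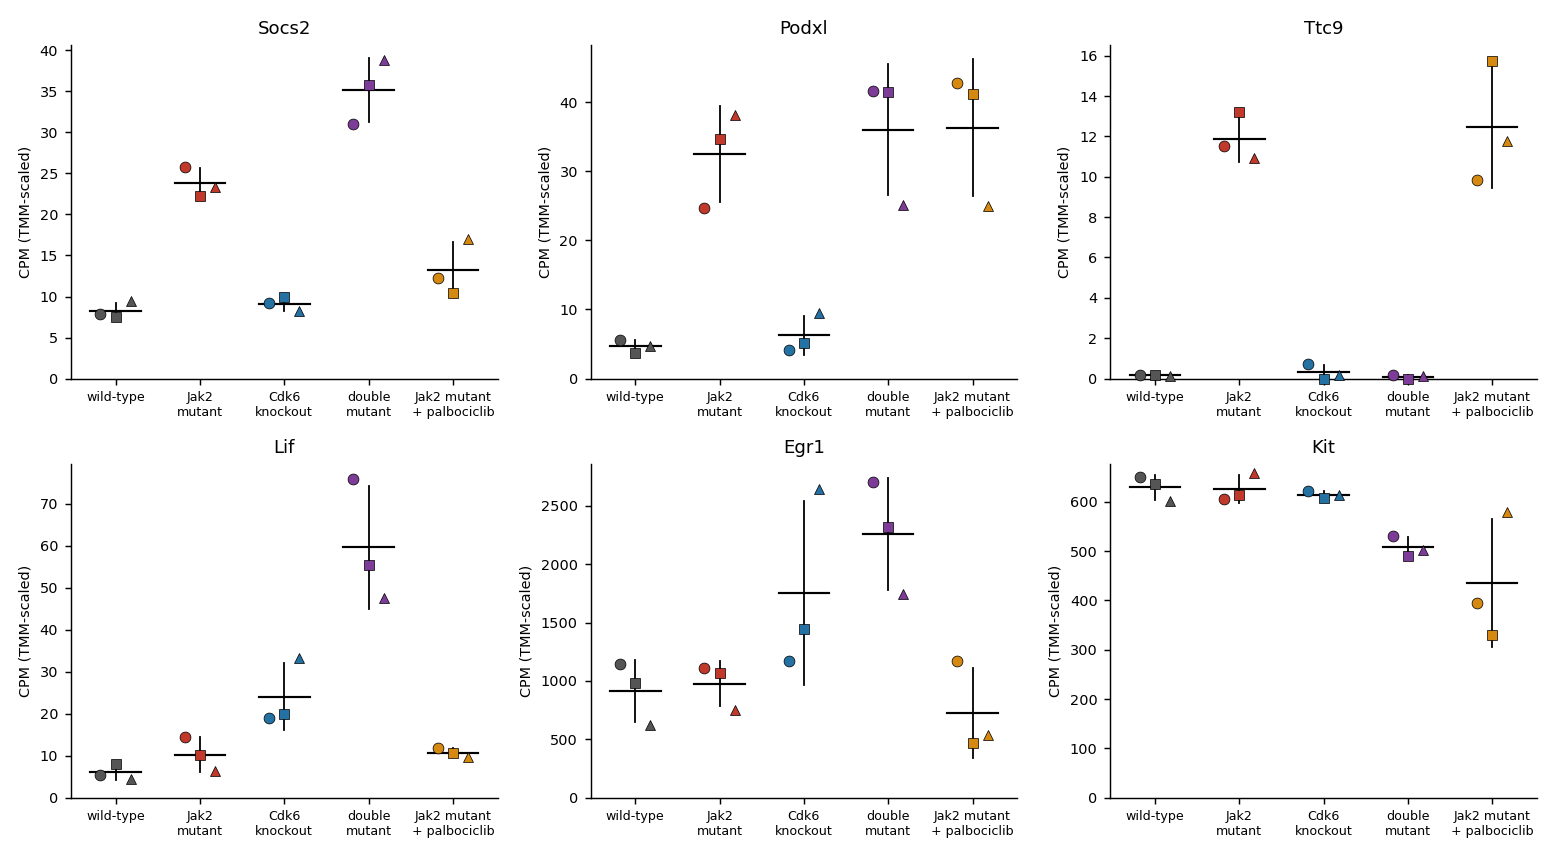
CPM of Socs2, Podxl, Ttc9, Lif, Egr1 and Kit in each of the 15 libraries by group (circle, square and triangle for replicates 1, 2 and 3; horizontal line, group mean; vertical line, ± SD). Socs2 averages 8.29 CPM in wild-type and 23.8 CPM in Jak2VF libraries, and Ttc9 averages 11.9 and 12.5 CPM in the Jak2VF and palbociclib-treated groups and at most 0.299 CPM in the others.

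Cdk6KO was compared with wild-type to ask what loss of Cdk6 changes when Jak2 is unmutated. Beyond Cdk6, which fell by 1.58 on the log2 scale (SE 0.16, 2.98-fold lower, edgeR adjusted p = 0.00310), few genes were called by edgeR. Lif, a cytokine of the interleukin-6 family (chromosome 11, 4257557 to 4272514), rose 3.97-fold from 6.03 ± 1.87 to 24.1 ± 7.93 CPM (log2 1.99, SE 0.32, edgeR adjusted p = 0.0430). Vmp1, an autophagy protein (chromosome 11, 86583865 to 86683836), rose 1.84-fold to 134.7 ± 20.3 CPM (edgeR adjusted p = 0.0246). Tlr3, a receptor for double-stranded RNA, fell from 6.40 ± 1.92 to 1.82 ± 0.0947 CPM, 3.50-fold (edgeR adjusted p = 0.0279). Lower by smaller folds were Syne2, a nuclear envelope protein (1.95-fold), and the ubiquitin ligase genes Ubr4 (1.495-fold), Birc6 (1.48-fold) and Herc2 (1.41-fold). With a length trend removed per library, 5 of the 9 called genes stayed called, and 3 of the 6 lower ones. Over all genes tested, the Spearman correlation of the change with exonic length was -0.0133, which does not exclude an effect of length on the genes called.

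A rise of 3.52 on the log2 scale (SE 0.43, edgeR adjusted p = 0.00913) was fitted for Gm17590, from 0.548 ± 0.255 to 6.28 ± 1.55 CPM. It lies on the opposite strand within Cdk6 (chromosome 5, 3472861 to 3480873), and both strands were counted together, so its counts cannot be assigned to it with certainty. This gene was chosen after its values were seen.

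No member of the gene lists below was called by edgeR. All 50 E2F and S-phase genes were lower, 19 at an unadjusted p under 0.05, and DESeq2 called 2. The median log2 change was -0.23 (camera, adjusted p = 1.56e-18), with adjusted p = 0.333 with an estimated correlation. Slbp, the histone mRNA binding protein, was at 97.99 ± 0.513 against 122 ± 6.83 CPM (edgeR adjusted p = 0.255), and Lig1, the replicative DNA ligase, at 259.7 ± 11.04 against 316.5 ± 11.3 CPM (edgeR adjusted p = 0.325). Of 44 G2/M genes 41 were lower, 5 at an unadjusted p under 0.05, and DESeq2 called 0 (camera, adjusted p = 1.56e-06; adjusted p = 0.499 with an estimated correlation). All 26 immediate early genes, which respond to growth factors and also to cell handling, were higher with a median log2 change of 0.81. Of these, 11 were at an unadjusted p under 0.05, 6 rose adjusted over the list alone, and DESeq2 called 3 (camera, adjusted p = 1.32e-11; adjusted p = 0.333 with an estimated correlation). Fosb, an AP-1 subunit, was at 1191 ± 296 against 314 ± 90.6 CPM (edgeR adjusted p = 0.0908), and Nr4a2, a nuclear receptor, at 15.5 ± 4.68 against 6.89 ± 0.515 CPM (edgeR adjusted p = 0.245).

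Dendritic and MHC class II genes were lower in Cdk6KO, with a median log2 change of -1.29 over 17 genes. Of these 8 were at an unadjusted p under 0.05, the same number fell adjusted over the list alone, and DESeq2 called 2 (camera, adjusted p = 9.80e-08; adjusted p = 0.333 with an estimated correlation). Zbtb46, a transcription factor of dendritic cells, was at 1.97 ± 0.365 against 6.76 ± 1.60 CPM (edgeR adjusted p = 0.138), and Xcr1, a chemokine receptor of cross-presenting dendritic cells, at 1.54 ± 1.39 against 8.69 ± 4.24 CPM (edgeR adjusted p = 0.289). All 19 B-lineage genes were lower, with 6 at an unadjusted p under 0.05 and 0 called by DESeq2 (camera, adjusted p = 1.64e-06; adjusted p = 0.333 with an estimated correlation). Of 30 megakaryocyte genes 28 were higher, 6 of them and 1 lower gene at an unadjusted p under 0.05, and DESeq2 called 3 (camera, adjusted p = 1.03e-06; adjusted p = 0.333 with an estimated correlation). NF-kB and JAK-STAT5 target genes were both higher (camera, adjusted p = 0.00243 for each; adjusted p = 0.499 and 0.333 with an estimated correlation). At an unadjusted p under 0.05 there were 5 members in each list, and DESeq2 called 0 and 3.

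The edgeR test called 9 genes between Cdk6KO and wild-type, 3 higher and 6 lower, while 1215 had an unadjusted p under 0.05 and DESeq2 called 97. Leaving out any 1 of the 6 libraries left 0 to 5 genes called. Without Cdk6KO library 2 even Cdk6 missed the threshold, and the G2/M, NF-kB and JAK-STAT5 lists lost their camera call without Cdk6KO library 3. The mean log2 CPM of immediate early genes was 7.55, 7.68 and 8.61 in Cdk6KO libraries 1, 2 and 3 and 6.70 to 7.35 in wild-type ones. Their difference went from 0.935 to 0.60 without that library, and that of G2/M genes from -0.17 to -0.0115 (-0.26 without Cdk6KO library 1). For NF-kB genes it went from 0.27 and for JAK-STAT5 genes from 0.26 to 0.17 without Cdk6KO library 3, and for megakaryocyte genes from 0.43 to 0.28 without wild-type library 2 or Cdk6KO library 2. No gene was called without wild-type library 3 and double-mutant library 1, a fit with fewer libraries. The log2 change of Cdk6 lay between -1.72 and -1.45 over all alternatives.

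The double mutant was compared with Jak2VF to ask what loss of Cdk6 changes in Jak2 mutant cells. Cdk6 fell by 1.55 on the log2 scale (SE 0.16, 2.93-fold lower, edgeR adjusted p = 0.00297). Lif rose 5.78-fold, from 10.3 ± 4.10 to 59.6 ± 14.6 CPM (log2 2.53, SE 0.31, edgeR adjusted p = 0.00581). Nlrp10, an innate immune receptor family member (chromosome 7, 108921852 to 108930178), rose 2.11-fold to 23.0 ± 0.729 CPM (log2 1.08, SE 0.15, edgeR adjusted p = 0.0172). Ttc9 fell from 11.9 ± 1.16 to 0.0954 ± 0.0902 CPM (edgeR adjusted p = 0.00297). Its counts were 357 and 3, a ratio of 123 with a 95% exact (Clopper-Pearson) counting interval of 41.6 to 598. The remaining called gene was Gm17590, within Cdk6 on the opposite strand, at 7.85 ± 1.97 against 0.735 ± 0.411 CPM (edgeR adjusted p = 0.00581), with the same uncertainty in its assignment.

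Mitotic genes were lower as a group. All 44 G2/M genes were lower with a median log2 change of -0.48, 37 at an unadjusted p under 0.05, and the same number fell adjusted over the list alone. None passed over all genes tested in edgeR, and DESeq2 called 7 (camera, adjusted p = 6.22e-34; adjusted p = 0.331 with an estimated correlation). Spc25, a kinetochore protein, was at 27.3 ± 3.96 against 43.6 ± 4.09 CPM, and Prc1, a protein of the spindle midzone, at 71.3 ± 4.23 against 97.6 ± 1.66 CPM (edgeR adjusted p = 0.163 for both). Of 50 E2F and S-phase genes 47 were lower, 12 at an unadjusted p under 0.05, 1 fell adjusted over the list alone, and DESeq2 called 1 (camera, adjusted p = 6.50e-10; adjusted p = 0.441 with an estimated correlation). Dendritic and MHC class II genes had a median log2 change of -1.27. Of 17 genes 10 fell adjusted over the list alone and DESeq2 called 1 (camera, adjusted p = 1.84e-09; adjusted p = 0.331 with an estimated correlation). H2-Aa and H2-Ab1, chains of an MHC class II molecule, were at 38.4 ± 13.4 against 154 ± 25.3 CPM and at 67.5 ± 20.8 against 220 ± 47.2 CPM (edgeR adjusted p = 0.316 and 0.322).

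Immediate early genes were higher, with a median log2 change of 1.12 over 26 genes, all in the same direction. At an unadjusted p under 0.05 there were 21, and 10 rose adjusted over the list alone, while edgeR called none over all genes and DESeq2 called 3 (camera, adjusted p = 1.05e-18; adjusted p = 0.333 with an estimated correlation). Fosb was at 1546 ± 429 against 444 ± 49.2 CPM (edgeR adjusted p = 0.163) and Nr4a2 at 29.9 ± 7.47 against 12.3 ± 1.07 CPM (edgeR adjusted p = 0.183). Unfolded protein and heat shock genes had 4 members that rose adjusted over the list alone, of 25 (camera, adjusted p = 4.97e-06; adjusted p = 0.426 with an estimated correlation). MYC and nucleolar genes had 1 of 34 (camera, adjusted p = 4.97e-06; adjusted p = 0.584 with an estimated correlation), and their camera call was lost without Jak2VF library 3. JAK-STAT5 target genes had 4 of 22 (camera, adjusted p = 0.000567; adjusted p = 0.331 with an estimated correlation). NF-kB genes did not pass (camera, adjusted p = 0.0971) but did without Jak2VF library 3 (camera, adjusted p = 0.0295) or double-mutant library 3 (camera, adjusted p = 0.0196). Ddit4, a stress-induced inhibitor of mTOR signalling, was at 207 ± 38.1 against 85.4 ± 9.83 CPM (edgeR adjusted p = 0.0859).

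For the double mutant and Jak2VF edgeR called 5 genes, 3 higher and 2 lower, with 1141 at an unadjusted p under 0.05 and 78 called by DESeq2. Leaving out any 1 of the 6 libraries gave 3 to 5 calls. Nlrp10 lost its call in each of these fits except the one without Jak2VF library 1, Lif without Jak2VF library 2 and Gm17590 without Jak2VF library 3. The difference in mean log2 CPM of MYC and nucleolar genes went from 0.22 to 0.076 without Jak2VF library 3. No gene was called without wild-type library 3 and double-mutant library 1, a fit with fewer libraries. Over all alternatives the log2 change lay between -1.72 and -1.44 for Cdk6, 2.28 and 2.85 for Lif, and -7.58 and -6.24 for Ttc9.

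**Figure D4:**
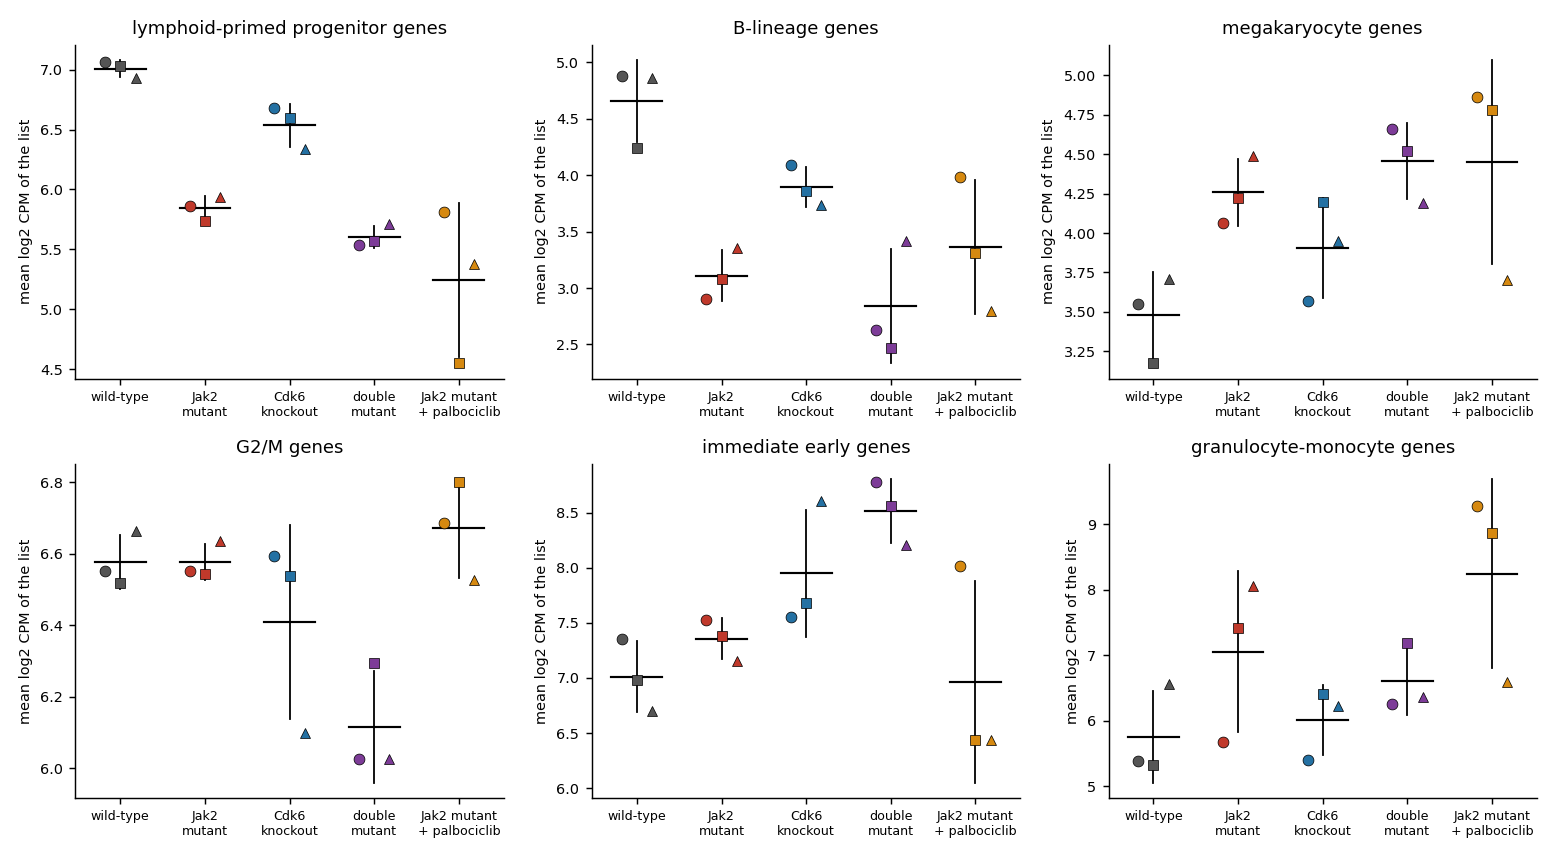
Mean log2 CPM of the lymphoid-primed progenitor, B-lineage, megakaryocyte, G2/M, immediate early and granulocyte-monocyte lists in each of the 15 libraries by group (circle, square and triangle for replicates 1, 2 and 3; horizontal line, group mean; vertical line, ± SD). Lymphoid-primed genes lie at 6.93 to 7.07 in wild-type and 5.74 to 5.94 in Jak2VF libraries, and granulocyte-monocyte genes spread from 6.595 to 9.28 among palbociclib-treated libraries.

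Palbociclib-treated Jak2VF libraries were compared with untreated Jak2VF libraries to ask what inhibition of the CDK4 and CDK6 kinases changes in Jak2 mutant cells. Every treated library was Xist-positive and every untreated one Y-positive, so treatment and sex of the mice cannot be told apart in this comparison. Socs2 fell 1.79-fold to 13.2 ± 3.36 CPM (log2 -0.84, SE 0.17, edgeR adjusted p = 0.0387). Tfrc, the transferrin receptor (chromosome 16, 32608920 to 32632794), rose 2.18-fold to 338 ± 79.7 CPM (log2 1.12, SE 0.19, edgeR adjusted p = 0.0369). C4b, a complement component (chromosome 17, 34728380 to 34743882), rose 6.86-fold to 9.96 ± 2.08 CPM (log2 2.78, SE 0.45, edgeR adjusted p = 0.0369). Cdk6 itself was at 691 ± 133 against 606 ± 9.64 CPM (edgeR adjusted p = 0.472).

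S-phase genes were higher in treated cells. Of 50 E2F and S-phase genes 5 rose and 45 did not pass, and 13 rose adjusted over the list alone. Rrm2, a ribonucleotide reductase subunit, rose 1.66-fold, Orc1 and Cdc6, which load the replicative helicase, rose 1.57-fold and 1.44-fold, and E2f8, a repressor of E2F targets, rose 1.33-fold (edgeR adjusted p 0.0387 to 0.0498). The median log2 change was 0.25 (camera, adjusted p = 4.58e-10), with adjusted p = 0.574 with an estimated correlation. G2/M genes did not pass (camera, adjusted p = 0.0603), and 3 of 44 were higher at an unadjusted p under 0.05. They passed, higher, without Jak2VF library 3 or without treated library 3 (camera, adjusted p = 0.0117 in the latter). Of 34 MYC and nucleolar genes 1 rose and 4 rose adjusted over the list alone (camera, adjusted p = 1.58e-07; adjusted p = 0.574 with an estimated correlation). Their difference in mean log2 CPM was 0.36, 0.22 without Jak2VF library 3 and 0.19 without treated library 2. Asns, which makes asparagine and is induced under amino acid stress, rose 2.94-fold, and Mt1, a metallothionein, rose 3.92-fold to 46.2 ± 22.7 CPM.

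Granulocyte and monocyte precursor genes were higher too. Of 37 granulocyte-monocyte genes 5 rose and 32 did not pass, and 11 rose adjusted over the list alone. Ms4a3, a marker of granulocyte and monocyte precursors, rose 5.73-fold to 179 ± 140.5 CPM, Ccr2, a monocyte chemokine receptor, rose 3.16-fold, and the neutrophil proteases Elane and Ctsg rose 2.86-fold and 2.43-fold. The median log2 change was 1.35 (camera, adjusted p = 1.58e-07), with adjusted p = 0.574 with an estimated correlation. Late granulocyte genes averaged 9.45 log2 CPM in treated and 7.97 in untreated libraries, with ranges of 6.54 to 11.27 and 5.17 to 10.02. Of 35 erythroid genes 29 were higher, with a median log2 change of 1.12, and 1 rose, Tfrc (camera, adjusted p = 0.0391; adjusted p = 0.962 with an estimated correlation). Their mean log2 CPM was 7.39, 6.25 and 4.31 in treated libraries 1, 2 and 3 and 4.53 to 5.80 in untreated ones. This camera call was lost without Jak2VF library 1 (adjusted p = 0.733) and treated library 2 (adjusted p = 0.144), and its direction turned without treated library 1 (adjusted p = 0.434). The difference in mean log2 CPM was 0.66 for erythroid genes (0.26 without Jak2VF library 1, -0.046 without treated library 1, 1.495 without treated library 3). It was 1.195 for granulocyte-monocyte genes (0.51, 0.68 and 2.02 without the same libraries). Treated library 1 also held Hba-a1, a hemoglobin gene, at 930 CPM and Igkc, an immunoglobulin light chain gene, at 1487 CPM, against at most 340 and 167 CPM in the other treated libraries. These 2 genes were chosen after their values were seen.

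Stem cell and lymphoid-primed progenitor genes were lower as lists, while B-lineage genes did not pass (12 of 19 higher, 0 called by edgeR or DESeq2, 2 at an unadjusted p under 0.05; camera, adjusted p = 0.763). Of 39 stem cell and quiescence genes 2 fell and 37 did not pass, and 16 fell and 2 rose adjusted over the list alone. Hlf, a transcription factor of stem cells, fell 2.22-fold to 122 ± 53.5 CPM and Mycn, a MYC family member, fell 1.82-fold (camera for the list, adjusted p = 4.52e-06; adjusted p = 0.574 with an estimated correlation). Of 19 lymphoid-primed progenitor genes 2 fell and 17 did not pass, and 9 fell adjusted over the list alone (camera, adjusted p = 8.40e-05; adjusted p = 0.574 with an estimated correlation). Those called were Lck, a T cell kinase (2.12-fold lower), and Ptprcap, a partner of the phosphatase CD45 (1.58-fold lower). The mean log2 CPM of the lymphoid-primed list was 5.81, 4.55 and 5.38 in treated libraries 1, 2 and 3 and 5.74 to 5.94 in untreated ones. Without treated library 2 its difference went from -0.60 to -0.25, and that of the stem cell list from -0.49 to -0.32. Outside the lists, Sgsm1 fell 3.90-fold, Cd200, an inhibitory surface ligand, 3.33-fold, Gimap7, a lymphoid GTPase, 3.25-fold, Serpini1, a protease inhibitor, 2.67-fold and Emp1, a membrane protein, 2.57-fold. Of 5 sex-linked genes measured 4 fell (camera, adjusted p = 0.00783; adjusted p = 0.574 with an estimated correlation), and this camera call was lost without palbociclib-treated library 3. JAK-STAT5 target genes, of which 1 fell, and NF-kB genes, of which edgeR called none, did not pass (camera, adjusted p = 0.953 and 0.861). The direction of both turned when single libraries were left out, and NF-kB genes passed without treated library 1 (camera, adjusted p = 0.000568).

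The edgeR test called 348 genes for palbociclib, 134 higher and 214 lower. The balance turned with the processing: 193 were higher and 184 lower with RLE scaling, 107 and 363 with upper-quartile scaling, and 201 and 179 without a filter on low counts. The count fell to 0 without Jak2VF library 1, 2 or 3 or without treated library 2, each in turn, and rose to 1125 without treated library 1 and 2737 without treated library 3. None of the 22 genes named stayed called in the fits that gave 0, and all 22 stayed called in the others. With Y-linked expression as a covariate 0 genes were called, and a fit of these 6 libraries alone called 5. Without treated libraries 1 and 2, which leaves treated library 3 alone, the log2 change was 0.25 for Rrm2, 0.62 for Asns, 0.67 for Tfrc, 0.99 for Ccr2, 1.02 for Mt1, -0.49 for Socs2 and -0.58 for Hlf, against 0.73, 1.56, 1.12, 1.66, 1.97, -0.84 and -1.15 with them. Over all alternatives the log2 change lay between -1.35 and -0.66 for Lck, -0.81 and -0.40 for Ptprcap, and 0.40 and 0.76 for Orc1. For Mycn it lay between -1.05 and -0.55 and for Sgsm1 between -2.525 and -1.23.

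Loss of Cdk6 and its kinase inhibition were set side by side through their shared untreated Jak2VF libraries. No gene was called by edgeR in both, where 0.0291 higher and 0.0310 lower genes would follow from the products of the edgeR counts. DESeq2, with 78 and 1355 calls, called 14 in both. Neither products nor simulations were made for DESeq2, so its 14 has no chance level to stand against. Unadjusted p under 0.05 was reached by 1141 genes on Cdk6 loss and 3306 on palbociclib. Simulations with no effect and the shared libraries gave a mean of 0.05 genes called higher and 0 called lower in both. Across the 13823 genes, which are not independent replicates, the covariance of both sets of log2 changes was 0.0563, against a simulated mean of 0.0856 (0.0757 to 0.101), and the correlation was 0.16 against 0.51. The simulations gave all groups the same spread per gene. In the data, the chi-square per degree of freedom between 2 libraries was 13.5 to 35.7 in Jak2VF and 66.3 to 159 in treated libraries. The simulated covariance and correlation thus decide nothing about opposed or shared effects. By edgeR, 1 of the 253 genes called in Jak2VF against wild-type was called in the reverse direction on Cdk6 loss (simulated mean 0). On palbociclib 12 of the 253 were called in reverse (simulated mean 0.05, range 0 to 1) and 6 in the same direction (simulated mean 0). DESeq2 called 640 genes in Jak2VF against wild-type, and of these it called 7 in reverse on Cdk6 loss and 65 on palbociclib. The DESeq2 counts were not simulated. Reversal of sign without regard to a call held for 57.7% of the 253 on Cdk6 loss and 54.9% on palbociclib. Simulations in which neither step had an effect gave 70.1% (68.2 to 72.2) and 70.8% (66.9 to 73.5), since the Jak2VF libraries enter both sides. They called 795.9 genes on average in the first comparison against 253 observed, so the shares rest on unlike gene sets. The observed shares of signs lay below both ranges, which rest on the same equal spread and so decide nothing. As the simulations held no effect of palbociclib, their counts of calls are near 0 in either direction and do not measure reversal.

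The double mutant was compared with Cdk6KO to ask what Jak2VF changes without Cdk6. Socs2 rose 3.86-fold, from 9.10 ± 0.837 to 35.2 ± 3.93 CPM (log2 1.95, SE 0.17, edgeR adjusted p = 0.000458). Podxl rose 5.81-fold to 36.03 ± 9.45 CPM (log2 2.54, SE 0.32, edgeR adjusted p = 0.0164) and Id1 6.25-fold to 13.4 ± 0.555 CPM (log2 2.64, SE 0.39, edgeR adjusted p = 0.0280). Fabp5, a fatty acid binding protein (chromosome 3, 10012548 to 10016607), rose 1.89-fold. St8sia1 fell 4.47-fold, Btla, an inhibitory lymphocyte receptor (chromosome 16, 45224315 to 45252895), fell 2.23-fold and Slc29a3, a nucleoside transporter, fell 1.39-fold. Socs2, Podxl, Id1 and St8sia1 were thus called in the same direction for Jak2VF with Cdk6 present and absent.

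Lymphoid lists were lower and megakaryocyte genes higher in this comparison as well, with no member called by edgeR over all genes. All 19 lymphoid-primed progenitor genes were lower, 14 of them adjusted over the list alone and at an unadjusted p under 0.05, and DESeq2 called 7 (camera, adjusted p = 5.02e-14; adjusted p = 0.188 with an estimated correlation). Of 19 B-lineage genes 10 fell adjusted over the list alone, 11 were lower at an unadjusted p under 0.05, and DESeq2 called 7 (camera, adjusted p = 4.68e-11; adjusted p = 0.188 with an estimated correlation). Of 30 megakaryocyte genes 9 rose adjusted over the list alone, 12 were higher at an unadjusted p under 0.05, and DESeq2 called 5 (camera, adjusted p = 6.03e-08; adjusted p = 0.291 with an estimated correlation). Of 39 stem cell and quiescence genes 5 rose adjusted over the list alone, and DESeq2 called 2 (camera, adjusted p = 2.40e-06; adjusted p = 0.323 with an estimated correlation). Socs2 and Id1 were the called members among 22 JAK-STAT5 target genes (camera, adjusted p = 0.000134; adjusted p = 0.188 with an estimated correlation). Of 44 G2/M genes 9 fell adjusted over the list alone, 24 were lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called 2 (camera, adjusted p = 9.18e-17; adjusted p = 0.291 with an estimated correlation). NF-kB genes were higher (camera, adjusted p = 0.0132; adjusted p = 0.525 with an estimated correlation), with 2 at an unadjusted p under 0.05, and lost that call without Cdk6KO library 2.

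Between the double mutant and Cdk6KO edgeR called 7 genes, 4 higher and 3 lower, with 1070 at an unadjusted p under 0.05 and 128 called by DESeq2. Leaving out a single library gave 19 calls without Cdk6KO library 3, 4 without double-mutant library 3 and 1, Socs2, without any of the other 4. Only Socs2 stayed called in each of these fits. The change correlated with exonic length over all genes tested (Spearman -0.176), and all 7 genes stayed called with a length trend removed per library. The difference in mean log2 CPM was 0.33 for the stem cell list (0.21 without Cdk6KO library 1, 0.54 without Cdk6KO library 3) and -0.29 for G2/M genes (-0.45 without Cdk6KO library 3).

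The double mutant was finally compared with palbociclib-treated Jak2VF, which sets the Cdk6 knockout against inhibition of the kinases. All 3 treated libraries and double-mutant library 1 were Xist-positive, while double-mutant libraries 2 and 3 were Y-positive. Sex of the mice is therefore largely confounded with this comparison. Cdk6 was 3.34-fold lower in the double mutant (log2 -1.74, SE 0.17, edgeR adjusted p = 0.000514). Lif was 5.57-fold higher, at 59.6 ± 14.6 against 10.7 ± 1.08 CPM (log2 2.48, SE 0.31, edgeR adjusted p = 0.00341), and Socs2 was 2.65-fold higher (log2 1.41, SE 0.17, edgeR adjusted p = 0.00273). Ttc9 was at 0.0954 ± 0.0902 against 12.5 ± 3.02 CPM (edgeR adjusted p = 0.00175). Gem, a small GTPase induced by growth stimuli (chromosome 4, 11704457 to 11714752), was 8.73-fold higher, Ddit4 was 3.36-fold higher, and the heat shock chaperones Hspa1b and Hspa1a were 8.43-fold and 7.96-fold higher.

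Proliferation genes were lower in the double mutant. Of 44 G2/M genes 31 were called lower and 13 did not pass, and 41 were lower adjusted over the list alone. Plk1, a mitotic kinase, was 1.81-fold lower, Ccnb1, cyclin B1, 1.85-fold, Spc25 1.72-fold and Ube2c, a ubiquitin conjugating enzyme of mitotic exit, 1.69-fold (camera for the list, adjusted p = 3.17e-21; adjusted p = 0.452 with an estimated correlation). Of 50 E2F and S-phase genes 29 were called lower and 21 did not pass, and 43 were lower adjusted over the list alone. Rrm2 was 2.03-fold, Ccne1, cyclin E1, 1.98-fold and E2f2, an E2F activator, 2.75-fold lower (camera for the list, adjusted p = 1.06e-20; adjusted p = 0.452 with an estimated correlation). Without treated libraries 1 and 2 the log2 change was -0.09 for E2f2 (edgeR adjusted p = 0.949), -0.24 for Ccne1 (edgeR adjusted p = 0.792), -0.32 for Ube2c and -0.54 for Rrm2, against -1.46, -0.99, -0.76 and -1.02 with them. Cdkn2c, an inhibitor of CDK4 and CDK6, was 2.35-fold lower, at 14.9 ± 3.85 against 34.8 ± 9.39 CPM.

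Immediate early and stem cell genes were higher in the double mutant and myeloid genes lower. Of 26 immediate early genes 10 were called higher, and 22 adjusted over the list alone. Nr4a1, a nuclear receptor, was 4.45-fold, Nr4a2 3.70-fold and Egr1, a zinc finger factor, 3.11-fold higher (camera for the list, adjusted p = 5.70e-13; adjusted p = 0.452 with an estimated correlation). Of 39 stem cell and quiescence genes, a list that also holds Nr4a1, Nr4a2 and Egr1, 11 were called higher, and 22 were higher and 1 lower adjusted over the list alone. Slamf1, the stem cell surface protein CD150, was 3.10-fold higher and Mpl, the thrombopoietin receptor, 2.36-fold (camera for the list, adjusted p = 1.19e-09; adjusted p = 0.452 with an estimated correlation). Of 37 granulocyte-monocyte genes 6 were called lower, and 32 adjusted over the list alone, among them Ms4a3 (4.77-fold), Ccr2 (4.07-fold) and Elane (3.13-fold) (camera for the list, adjusted p = 6.02e-09; adjusted p = 0.452 with an estimated correlation). Late granulocyte genes averaged 7.10 log2 CPM in the double mutant (6.44 to 8.41) and 9.45 in treated libraries. Fn1, fibronectin, was 18.5-fold lower (log2 -4.21, SE 0.95, edgeR adjusted p = 0.0279), and Vcan, a matrix proteoglycan of monocytes, was at 0.606 ± 0.254 against 11.4 ± 12.8 CPM. Without treated libraries 1 and 2 the log2 change was -0.97 for Fn1 (edgeR adjusted p = 0.754) and -0.52 for Vcan (edgeR adjusted p = 0.905). Of 19 lymphoid-primed progenitor genes 4 were called higher (camera, adjusted p = 0.0159; adjusted p = 0.732 with an estimated correlation), and that camera call was lost without palbociclib-treated library 2. Its difference in mean log2 CPM was 0.36, 0.64 without treated library 1 and 0.010 without treated library 2. For granulocyte-monocyte genes it was -1.645, and -2.47 without treated library 3. NF-kB genes did not pass (camera, adjusted p = 0.236) but did without treated library 1 (camera, adjusted p = 7.48e-06), and their direction turned without treated library 3.

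In this comparison edgeR called 1016 genes, 504 higher and 512 lower. This balance also turned with the processing, to 713 higher and 345 lower with upper-quartile scaling, and to 422 and 846 without a filter on low counts. The count was 16, 160 and 41 without double-mutant library 1, 2 and 3, and 1190, 58 and 3761 without treated library 1, 2 and 3. With Y-linked expression as a covariate 5 genes were called, and 16 without wild-type library 3 and double-mutant library 1.

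The interaction of both changes asked whether loss of Cdk6 acts differently in Jak2 mutant and in unmutated cells. The edgeR test called 0 genes, with 409 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0560, limma-voom called 0, and DESeq2 called 16. As a list, G2/M genes had a median log2 difference of -0.33, lower in 42 of 44 members and by 9 at an unadjusted p under 0.05 (camera, adjusted p = 1.89e-13; adjusted p = 0.957 with an estimated correlation). NF-kB genes did not pass (camera, adjusted p = 0.328). Effects of Cdk6 loss in Jak2 mutant and unmutated cells were thus not shown to differ for any single gene in the main edgeR fit. Without the palbociclib-treated libraries edgeR called 4 genes, with only the groups compared 4, and in its other fits 0 or 1. Ttc9 changed by -6.78 on Cdk6 loss in Jak2 mutant cells and by 0.85 in unmutated ones, where it was at 0.154 and 0.299 CPM. It was not called for the interaction in the main fit.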

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

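The tests on late granulocyte genes as a covariate, on transcript length and on progenitor and mature B cell genes were chosen after the result was seen, as were the fits with a Y-linked covariate, while the shifts in Xist-positive libraries and the splits were set before. The deciding bound of both granulocyte covariate tests was revised after its result was seen. In its first form, that bound also asked that over 50% of the calls stay called, under which the palbociclib test would have decided nothing. Neither test is taken to decide a cause here, since each used genes called by the comparison under test.

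Cdk6 loss moved 9 gene lists differently in Jak2 mutant and unmutated cells by camera on the interaction, which is why they are given here. G2/M genes had a median log2 difference of -0.33 (median change -0.13 in unmutated and -0.48 in mutant cells; adjusted p = 1.89e-13), with 42 of 44 members lower. MYC and nucleolar genes differed by 0.21 (-0.01 and 0.21; adjusted p = 7.56e-05), erythroid genes by 0.48 (-0.42 and 0.14; adjusted p = 0.00225), and unfolded protein and heat shock genes by 0.25 (0.06 and 0.20; adjusted p = 0.00404). Mast and basophil genes differed by -0.61 (0.35 and -0.15; adjusted p = 0.00410), granulocyte-monocyte genes by -0.98 (0.28 and -0.86; adjusted p = 0.0198), and megakaryocyte genes by -0.29 (0.40 and 0.18; adjusted p = 0.0366). B-lineage genes differed by 0.46 (-0.91 and -0.22; adjusted p = 0.0366) and E2F and S-phase genes by 0.066 (-0.23 and -0.19; adjusted p = 0.0407). No member was called by edgeR; at an unadjusted p under 0.05 there were 9 G2/M, 1 B-lineage and 1 mast and basophil gene, and none of the 9 lists passed with an estimated correlation (adjusted p = 0.957 for each). Leaving out single libraries kept 4 to 8 of these 9 lists called by camera, with 4 without Jak2VF library 3, and only G2/M in all 12 fits. Without Jak2VF library 3 the calls of MYC and nucleolar (camera, adjusted p = 0.128), unfolded protein and heat shock (adjusted p = 0.384) and granulocyte-monocyte genes (adjusted p = 0.527) were lost. So were those of megakaryocyte and of E2F and S-phase genes (camera, adjusted p = 0.769 for the latter). Other splits of the 12 libraries say nothing about single genes here, because any split calls at least as many as the real 0 (100 of 100 drawn splits). The highest other split called 444. The drawn splits mixed libraries of all the groups compared, so the effect of Jak2VF itself can enter such a count, and its cause was not tested.

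The genes called in palbociclib-treated against untreated Jak2VF cells were weighed first, because the treated libraries are all Xist-positive and differ in late granulocyte genes. Mature granulocyte RNA in treated libraries 1 and 2 stays open as a cause, although the sort removed cells positive for CD11b and Gr-1. Kit, the gene of the sort marker c-Kit, was at 395 and 330 CPM in treated libraries 1 and 2 and at 580 CPM in library 3. It was at 606 to 659 CPM in untreated Jak2VF and 491 to 531 CPM in double-mutant libraries. This gene was chosen after its values were seen. With late granulocyte genes as a covariate, 95.1% of the median fold was kept (log2 0.67 to 0.64, median SE 0.147 to 0.142). The genes were selected by this same comparison, and for 345 of 348 the libraries did not overlap between the groups. A kept fold was thus largely set beforehand and decides nothing about granulocyte RNA. Only 125 of 348 genes stayed called. Before, all adjusted p lay between 0.0369 and 0.05, and the covariate also uses a residual degree of freedom, but which of these ended the calls was not tested. Sex of the mice cannot be told apart from treatment. The called autosomal genes (328) shifted by 1.66% of their palbociclib change in Xist-positive double-mutant library 1, but by 14.6% in wild-type library 3, against -1.34% and 1.62% in double-mutant libraries 2 and 3, and those 2 Xist-positive libraries come from other groups. With a Y-linked covariate 94.8% of the fold was kept (log2 0.62) but the SE rose from 0.146 to 0.223 and 0 genes were called. Sex, granulocyte RNA and the drug all stay open.

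Long transcripts among the genes lower in Jak2VF were weighed next. Of 175 genes called lower, 81 had exonic lengths of at least 9089 bases, a length that 10% of tested genes reach. With a length trend removed per library, 39.5% of these 81 stayed called (32), against 76 of the other 94 lower genes. Their median log2 change went from -0.52 to -0.38, so 73.6% of it was kept. A trend of length between libraries may explain part of the calls among long genes, and whether it comes from RNA quality or from the cells was not tested and stays open.

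The fall of lymphoid and B-lineage genes in Jak2VF was weighed last. The 9 progenitor genes taken as not expressed by mature B cells, such as Rag2, had a median log2 change of -1.86 (6 called lower). They were chosen after the result was seen, and genes named above as lower, such as Rag1, are among them. Mature B cells left in the wild-type libraries would not account for a fall of such genes. This rests on how the genes were chosen, since no level in mature B cells was measured, and it decides nothing beyond them. That says nothing about whether such cells were present. For genes that mature B cells express this cause stays open. The 12 measured had a median of -0.89 (2 called lower), and the most abundant moved apart: Ighm (2884 to 926 CPM, log2 -1.64) and Igkc (923 to 221 CPM, log2 -2.06) were lower, while Cd74 (360 to 341 CPM, log2 -0.08) was nearly level. Progenitors and dendritic cells also express some of these genes, and the sort removed CD19-positive cells. Dilution by granulocyte RNA was not decided. With late granulocyte genes as a covariate, 94.8% of the median fold of the called members was kept (log2 size 1.90 to 1.79, 13 of 14 called). These members were selected for being lower in Jak2VF, so a kept fold was largely set beforehand. In Jak2VF library 1 late granulocyte genes were at 5.17 log2 CPM, within the wild-type range of 5.02 to 7.30. A smaller share of lymphoid-primed cells within the sorted fraction and lower expression per cell both stay open, untested in bulk RNA.

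Other splits of the 6 libraries of each comparison are too few (10) for a share under 0.05. The real split of Jak2VF and wild-type called 253 genes and the highest other 2, so 1 split, the real one, called as many. In the same way 1 split called as many for Cdk6KO and wild-type (9, highest other 0), the double mutant and Jak2VF (5, highest other 0), the double mutant and Cdk6KO (7, highest other 1) and the double mutant and treated Jak2VF (1016, highest other 791). For palbociclib 2 splits called as many as the real 348. The other, with 763 genes, set treated libraries 1 and 2 with Jak2VF library 3 against the rest, which points to a structure of the samples that follows the late granulocyte genes. The split with 791 genes set double-mutant libraries 1 and 3 with treated library 3 against the rest, along the same structure.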

How the results depend on the processing

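All counts here are genes with an adjusted p under 0.05, in the order Jak2VF with wild-type (253), Cdk6KO with wild-type (9), double mutant with Jak2VF (5), palbociclib-treated with untreated Jak2VF (348), double mutant with Cdk6KO (7), double mutant with treated Jak2VF (1016), interaction (0), and apart from limma-voom and the fits without single libraries only counts that moved over 1.5 times are given. The fits without palbociclib libraries, without Xist-positive libraries, with Y-linked or late granulocyte covariates and with the length trend removed were chosen after seeing the data. Unless a cause is named, the cause was not tested.

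DESeq2 called 640, 97, 78, 1355, 128, 2363 and 16 genes, of which 245, 9, 5, 345, 7, 1002 and 0 were also called by edgeR. Limma-voom called 207, 9, 5, 253, 5 and 769 in the first 6. DESeq2 called 14 genes in both Cdk6 loss and palbociclib (0 by edgeR). Of its own 640 calls for Jak2VF, 7 and 65 moved back on Cdk6 loss and palbociclib (1 and 12 of 253 by edgeR). With the replicate number as a replicate block, Jak2VF with wild-type had 168 and palbociclib 107. RLE scaling gave 1 for the interaction. Without a filter on low counts there were 17 for Cdk6KO, 12 for the double mutant with Cdk6KO and 1 for the interaction.

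Without the 3 palbociclib libraries there were 908, 55 and 11 for the first 3, 140 for the double mutant with Cdk6KO and 4 for the interaction. Leaving out treated libraries 1 and 2 gave 851, 49, 8, 0, 124 and 20 for the first 6. The treated libraries differ most among themselves, and all libraries share 1 spread in the fit. Leaving out wild-type library 3 and double-mutant library 1 gave 38, 0, 0, 14, 1 and 16 in the same order, with fewer libraries in the groups. Only the libraries of the groups compared gave 697, 44, 29, 5, 41, 6 and 4. The Y-linked covariate gave 2 for Cdk6KO, 0 for palbociclib, 1 for the double mutant with Cdk6KO and 5 with treated Jak2VF. The late granulocyte covariate gave 15 for Cdk6KO, 135 for palbociclib and 165 for the double mutant with treated Jak2VF. With the length trend removed there were 5 for Cdk6KO and 123 for palbociclib.

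Leaving out single libraries gave 52 to 111, 0 to 5, 3 to 5, 0 to 2737, 1 to 19, 16 to 3761 and 0 to 1. Of the 744 values of the named genes in these fits, 399 kept their direction and side of the threshold, 333 fell short of it and 12 changed direction. Of 122 values each, 110 stayed under DESeq2 and 12 newly passed, 120 stayed with RLE scaling, 117 without a filter, 116 with upper-quartile scaling, 102 with the length trend removed, 99 with limma-voom, 96 with the granulocyte covariate and 91 with the replicate block. Fewer stayed without treated libraries 1 and 2 (70; 46 fell short), with only the groups compared (66 of 121; 47), with the Y-linked covariate (59; 62) and without wild-type library 3 and double-mutant library 1 (41; 80). Of 189 gene list tests camera called 93, against 0 with an estimated correlation and 17 with fry. No scaling moved the median of all genes by over 0.1 on the log2 scale.

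Direction turned only for values that were not called, apart from the erythroid list on palbociclib. Jak2 in Cdk6KO with wild-type (log2 -0.0045) became 0.0085 with upper-quartile scaling, 0.00025 without the 3 palbociclib libraries, 0.0039 without treated libraries 1 and 2, 0.060 without wild-type library 3 and double-mutant library 1, 0.023 with the Y-linked covariate and 0.00071 with only the groups compared, and -0.075 to 0.058 without single libraries. Jak2 in the double mutant with treated Jak2VF (-0.055) became 0.017 with upper-quartile scaling, 0.039 with the granulocyte covariate and 0.052 without treated libraries 1 and 2, and -0.16 to 0.085 without single libraries. Jak2 on palbociclib ranged from -0.18 to 0.061. Cdk6 in the interaction (0.028) became -0.049 with the granulocyte covariate and -0.047 with the length trend removed, and -0.13 to 0.17 without single libraries. Cdk6 in the double mutant with Cdk6KO ranged from -0.091 to 0.22.

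List directions turned for anti-apoptotic genes in Jak2VF with the replicate block (camera, adjusted p = 0.933) and for JAK-STAT5 genes on palbociclib with upper-quartile scaling (adjusted p = 0.948) and the replicate block (adjusted p = 0.993). Without single libraries, camera adjusted p ranged from 0.0444 to 0.899 for E2F and S-phase, 0.465 to 0.964 for G2/M and 0.756 to 0.958 for anti-apoptotic genes in Jak2VF with wild-type. On palbociclib the ranges were 0.000568 to 0.881 for NF-kB, 0.294 to 0.968 for JAK-STAT5, 0.218 to 0.987 for B-lineage genes, whose direction turned without treated library 1, and 6.75e-07 to 0.733 for erythroid genes, and 7.48e-06 to 0.865 for NF-kB in the double mutant with treated Jak2VF.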

Other observations

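The genes and libraries in this part were chosen after their values were seen. Flt3, a cytokine receptor of multipotent progenitors, was at 1131 ± 92.0 CPM in wild-type, 658 ± 42.9 in Jak2VF, 993 ± 54.1 in Cdk6KO, 590 ± 75.2 in double-mutant and 337 ± 156 in palbociclib-treated libraries. Dntt, a DNA polymerase of receptor gene assembly, was at 2356 ± 521, 983 ± 42.4, 1589 ± 364, 635 ± 89.9 and 362 ± 222 CPM. For Jak2VF with wild-type these 2 genes missed the threshold (edgeR adjusted p = 0.150 and 0.142), while Notch1, a receptor of lymphoid fate (log2 -1.13, edgeR adjusted p = 0.0122), and Mn1, a transcriptional cofactor (log2 -1.86, edgeR adjusted p = 0.00603), passed it.

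Ttc9 was at 11.9 CPM in Jak2VF and 12.5 CPM in treated Jak2VF, and at 0.154, 0.299 and 0.0954 CPM in wild-type, Cdk6KO and double-mutant libraries. Of its 12 measured neighbours within 1 Mb, Smoc1 was the single gene called for Jak2VF, in the other direction (log2 -1.47, edgeR adjusted p = 0.0186). Near Cdk6, Gm17590 was at 0.548, 0.735 and 0.706 CPM in wild-type, Jak2VF and treated libraries and at 6.28 and 7.85 CPM in Cdk6KO and double-mutant libraries. Akap9, in the same region, was called for Jak2VF with wild-type (log2 -0.45, edgeR adjusted p = 0.0354).

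Eef2 was the most counted gene in 13 of 15 libraries, and S100a9 in treated libraries 1 and 2 (1.499% and 0.882% of counts). The first principal components held 39.4% and 13.1% of the variance.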
